A study of Mus musculus with 6 samples.

How the data were processed

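The data are 6 two-colour spotted oligonucleotide arrays of 25344 spots in 48 blocks. Each array set the pooled RNA of 3 Ts1Cje embryos against that of 3 wild-type littermates, from neurospheres of embryonic day 14 neocortex, with 5 µg from each embryo and 15 µg labelled, per the labels. Litters 1, 2 and 3 each had 1 array with Ts1Cje in Cy5 and 1 with the dyes exchanged, so the replicate was the litter (n = 3), and both arrays of a litter are technical repeats of 1 pair of pools. The file headers of 5 arrays give a scanning day, and it is 1 day for those 5, so no scanning batch could be compared.

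The scanner files hold the median foreground and local background intensity of each spot at 635 nm (Cy5) and 532 nm (Cy3), on a linear scale with no background subtraction or normalization, per the file headers (Mapix 2.0). The percent of saturated pixels per spot was deposited as the scanner software wrote it, per the file headers, and set no filter here. The array of litter 3 with Ts1Cje in Cy5 came as a short table with intensities but no background SD and no spot quality codes. The series value table holds the authors' normalized log2 of Cy5 over Cy3 as deposited, without a change of sign for the exchanged dyes, and the method of normalization is not stated. Its column medians lie between -0.0121 and 0.012, and its values correlated with the log ratios computed here at 0.81 to 0.98 across probes, which are not independent replicates. No file names a genome build, so no coordinates are given.

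Foreground intensities were corrected with normexp (offset 50) and log ratios normalized within each array by loess (span 0.3, control and bad spots at weight 0) in limma 3.58.1 under R 4.3.3. Ratios of the arrays with Ts1Cje in Cy3 were turned in sign, and each litter's pair of arrays was averaged. A spot was bad at a quality code of -100 or, on the short table, where the authors' value was empty. Probes were kept when, on at least 3 arrays, the spot was not bad and at least 1 channel exceeded the background by 2 background SD (1.5 times the background on the short table); 9151 of 24107 probes passed, and 7861 of these had a value in each litter. Median foreground over background was 2007 over 1356 (Cy5) on the dimmest array and 3538 over 2056 on the brightest, and the number of arrays limits the precision. Between 52 and 126 probes per array reached the scanner ceiling in a channel.

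Of the probes, 15685 were named by RefSeq accession, 2963 by symbol and 1694 by an older symbol; 27 had a symbol that matched nothing and 3738 had none. The reference table (GRCm38 patch 6) served only for names and for the order of genes along chromosomes. A gene with several probes went by its brightest probe.

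Probes were tested with limma (an intercept on the 3 litter values, moderated by eBayes), two-sided, with the Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera (cameraPR, preset correlation 0.01), camera with an estimated correlation, and fry, with adjustment over the 22 lists outside the copy number groups. Camera compares a list with all other genes. The 3 copy number lists, of trisomic chromosome 16, proximal chromosome 16 and distal chromosome 12, were tested singly. Windows of 15 genes were compared with 10000 permutations of gene positions, and trisomic with proximal genes by a two-sided permutation test.

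The tests, the gene lists, most alternative settings and the rule for named genes were fixed before the data were examined. The rule took up to 10 genes in each direction that passed and had 1 sign in the 3 litters, with places left filled by the smallest unadjusted p. It added the 8 highest and 4 lowest trisomic genes, the 2 highest and 2 lowest of the other copy number lists by log2 ratio and of each further list by moderated t, and Sod1, Dyrk1a, Olig1, Olig2, App, Ets2, Hmgn1, Cdkn1a, Cdkn1b, Ccnd1 and Mki67. No fold is given for a gene whose lower channel was above background on no array.

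The method was tested on simulated litters, with probe variances drawn from the distribution fitted to these arrays. Genes were simulated as independent of each other and without a dye effect. It recovered 6% of probes moved 1.5-fold, 76% of those moved 2-fold and 100% of those moved 4-fold or 8-fold, with 4.73% of calls on unmoved probes. A list of 22 genes moved 1.5-fold was called in 100% of simulations. These shares hold for independent genes and do not cover lists whose genes move together.

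Alternative settings fixed then were other background corrections (none, plain subtraction), other normalizations (median centring, print-tip loess, Aquantile), no filter or a filter on each array, the 6 arrays with litter as a random replicate block with and without a dye term, each dye orientation alone, leaving out each litter, leaving out the short table, the authors' values, a threshold of 0.1, probes of a gene averaged, eBayes with trend and robust options, and an estimated correlation. Added after seeing the data were a litter value from 1 array where the other spot was bad, centring of each litter, and the alternatives to the window scan.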

Results

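Two-colour oligonucleotide arrays compared RNA from neural precursor cells of Ts1Cje mice with RNA from wild-type littermates. Ts1Cje is a mouse model of Down syndrome with 3 copies of the distal part of chromosome 16, from below Sod1 to Zbtb21. The segment is carried on a translocation to chromosome 12, whose last genes are left in 1 copy. The cells came from the neocortex of embryos at embryonic day 14 and were grown as neurospheres, floating clusters kept in epidermal and fibroblast growth factor, for at least 4 passages. There were 3 litters, and for each litter the pooled RNA of 3 Ts1Cje embryos was hybridised against the pooled RNA of 3 wild-type embryos. Each pair of pools was measured on 2 arrays with the dyes exchanged, giving 6 arrays: 3 with Ts1Cje in Cy5 and 3 with Ts1Cje in Cy3. The 2 arrays of a litter share their RNA and counted as 1 replicate. Values below are log2 ratios of Ts1Cje over wild type, as the mean ± SD of 3 litters unless stated otherwise, so that a doubling is 1.

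Of 24107 probes outside control spots, between 23.3% and 36.7% were above background in at least 1 channel on the 5 arrays with full scanner output. On the litter 3 array with Ts1Cje in Cy5, which has no background SD and was judged by a ratio, this share was 59.2%. After the filter, 7861 probes were tested, and 7015 of them named 6731 genes. The small number of litters limits the precision. Across the tested probes, the 2 arrays of a litter correlated with r = 0.36 in litter 1, 0.47 in litter 2 and -0.07 in litter 3. Arrays of litters 2 and 3 with the same dyes correlated more closely, at 0.53 and 0.55. The dye effect had an SD over probes of 0.22, as large as that of the mean ratio (0.22), and it cancels in the mean of a dye-swap pair. Litter means correlated at -0.20 between litters 1 and 2, at 0.13 between litters 1 and 3, and at 0.47 between litters 2 and 3. These correlations are across probes, which are not independent replicates.

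The first question was whether genes of the triplicated segment were higher in the cells labelled Ts1Cje. Of the 68 genes listed for the segment, 22 were measured, and their median log2 ratio was 0.14 (1.10-fold), with 13 above 0. The log2 ratio of 3 copies over 2 is 0.58, and 3 members exceeded it: Son, an RNA splicing protein, at 0.88 ± 0.30 (1.83-fold), Atp5o, a subunit of mitochondrial ATP synthase, at 0.64 ± 0.54, and Olig1, a transcription factor of the oligodendrocyte lineage, at 0.63 ± 0.33. Olig2, its neighbour and a regulator of motor neuron and oligodendrocyte fate, stood at 0.44 ± 0.32, the interferon gamma receptor subunit Ifngr2 at 0.46 ± 0.15, and the kinase Dyrk1a at 0.37 ± 0.17. These 6 genes were above 0 in all 3 litters, and Son, Olig1, Olig2, Ifngr2 and Dyrk1a were above 0 on 6 of 6 arrays. Itsn1, an endocytic scaffold, followed at 0.30 ± 0.46, and Mrps6, a mitochondrial ribosomal protein, at 0.25 ± 0.51. The lowest were the protease Tmprss2 at -0.29 ± 0.96, the interferon-induced Mx1 at -0.24 ± 0.45, Hlcs, which attaches biotin to carboxylases, at -0.22 ± 0.31, and the kinase Hunk at -0.17 ± 0.14. The transcription factor Ets2 was at -0.11 ± 0.41, while Hmgn1, a nucleosome-binding protein, was not among the genes named on the array.

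As a group the trisomic genes were higher in Ts1Cje with the preset correlation (camera p = 0.011). The call was lost with an estimated correlation between genes of 0.08 (camera p = 0.231), and fry gave p = 0.241. Over all probes tested none of the 22 passed in limma, with 6 at an unadjusted p under 0.05, and 1 passed when adjusted over the list alone, Son (adjusted p = 0.0195), which lost this call on the 3 arrays with Ts1Cje in Cy5, where it stood at 0.50. A second probe for Son, above background in Ts1Cje on 2 arrays, gave 0.66. The litter medians of the list were 0.31, 0.0030 and 0.12, and leaving out litters one at a time moved the median from 0.03 (without litter 1) to 0.23 (without litter 2).

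**Figure D1:**
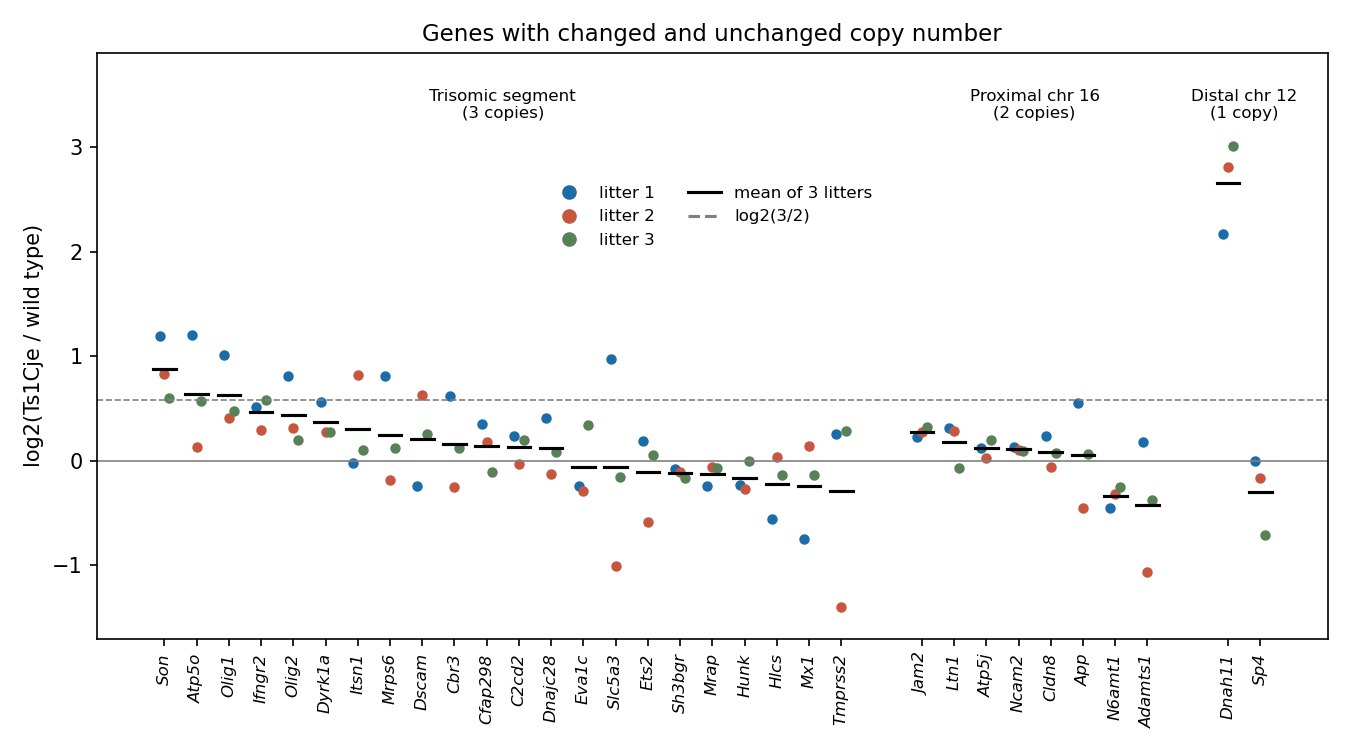
Log2 ratios of Ts1Cje over wild type (vertical axis) for the measured genes of the trisomic segment, of proximal chromosome 16 and of distal chromosome 12 (horizontal axis); points are the 3 litters, black bars their mean, and the dashed line the log2 ratio of 3 copies over 2. Of the trisomic genes 3 have means above the dashed line, and Dnah11 stands at 2.66.

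Genes of chromosome 16 on the centromere side of the segment are in 2 copies in Ts1Cje and served as a control. The 8 measured ones had a median of 0.10 and a mean of 0.01 and did not pass (camera p = 0.67, and 0.742 with an estimated correlation). The highest were the junction protein Jam2 (0.28 ± 0.05) and the ubiquitin ligase Ltn1 (0.18 ± 0.22), and the amyloid precursor App stood at 0.06 ± 0.50, with a second probe at -0.0060. Adamts1, a secreted protease, was lowest at -0.42 ± 0.62. N6amt1, a methyltransferase, was not well above background in Ts1Cje on any array and is given no fold. None of the 8 passed over all probes or adjusted over the list alone. The mean of the trisomic genes exceeded that of the proximal genes by 0.14, 0.14 and 0.15 in the 3 litters (mean difference 0.14 ± 0.0066), larger than the spread between litters. The proximal mean was pulled down by its 2 members below 0. By medians the lists lay closer, at 0.14 against 0.10. Litter medians were 0.31, 0.0030 and 0.12 for the trisomic list, against 0.20, -0.01 and 0.07 for the proximal list. Across genes the difference of the means did not pass (two-sided permutation p = 0.262), and an exact sign-flip test over 3 litters cannot give less than 0.25.

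Without the list, gene order was read along each chromosome. Among 6437 windows of 15 neighbouring measured genes, the 5 highest medians (0.25 each) all lay around the segment. They ran from windows starting at Krtap8-1 or Sod1 to the window ending at Sh3bgr. These windows overlap and share the value of Mrps6 as their median, so they are not separate results. The windows from Hunk to Cbr3 and from Mrap to Hlcs, which lie between them, had 0.16. The highest median did not pass a permutation of gene positions (p = 0.109). From just below Sod1 to the end, chromosome 16 held 23 measured genes with a median of 0.14, 14 of them above 0, against -0.0035 for the 169 genes of the rest of the chromosome, of which 83 were above 0. No chromosome as a whole differed from the others after adjustment, the smallest adjusted p being 0.146 for chromosome 6 (median -0.04). The window result passed in 5 of 19 alternatives, most clearly without litter 2, where the highest median was 0.41, again in the segment (permutation p = 0.000999).

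**Figure D2:**
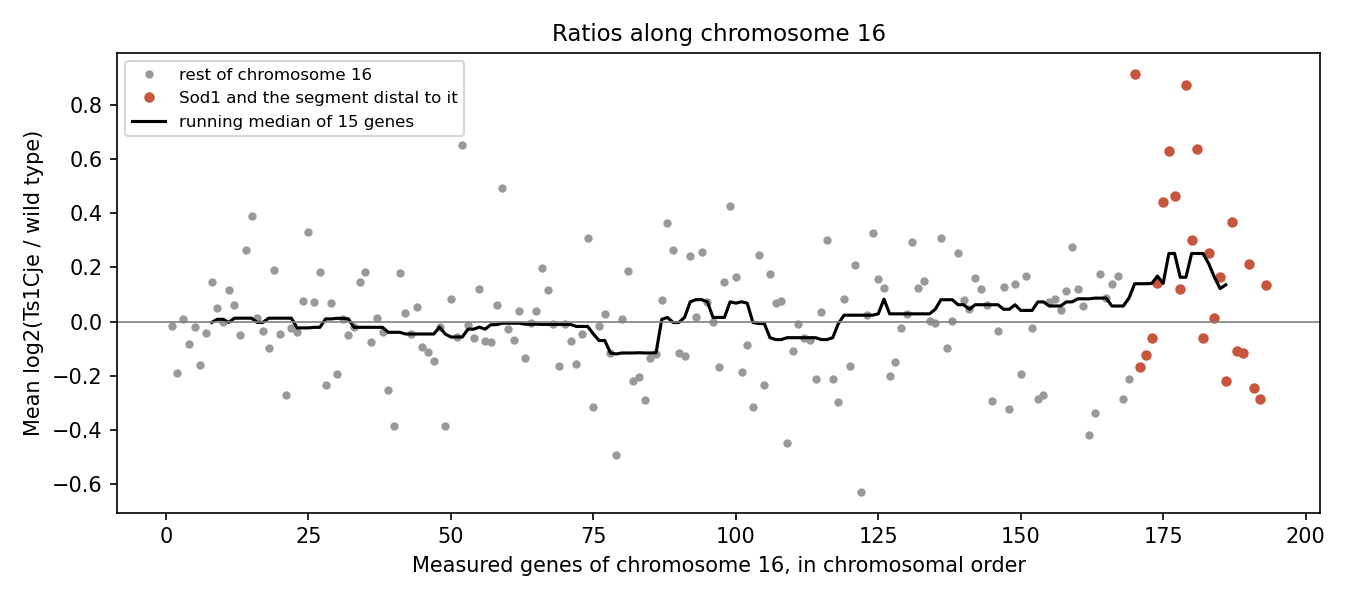
Mean log2 ratio of Ts1Cje over wild type (vertical axis) of each measured gene of chromosome 16 in chromosomal order (horizontal axis); red points are Sod1 and the genes distal to it, and the line is the running median of 15 genes. The running median reaches its highest value, 0.25, within the segment.

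Distal chromosome 12, present in 1 copy, was represented by 2 measured genes. Dnah11, an axonemal dynein heavy chain of motile cilia (Dnahc11 in the files), was higher in Ts1Cje by 2.66 ± 0.44 (6.32-fold), and Sp4, a transcription factor, stood at -0.29 ± 0.37. Dnah11 was higher in each litter (2.17, 2.81 and 3.01) and on each of the 6 arrays (1.99 to 4.03). The Ts1Cje channel of Dnah11 was above background on all 6 arrays and its wild-type channel on 3. The median of this pair was 1.18, with no group test for so few genes.

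Over all probes, Dnah11 was the single call: 1 of 7861 probes passed (limma adjusted p = 0.0119), and the next smallest adjusted p was 0.58. An unadjusted p under 0.05 was reached by 462 probes, 5.88% where chance gives 5%, and 334 of them were higher in Ts1Cje and 128 lower. This balance depended on the litters: without litter 1, whose median over all genes was 0.09, 478 of 1215 were higher, without litter 3 the count was 244, and with each litter centred on its median 286 of 466 were higher. All 3 litters had the same sign for 1334 probes on the higher and 864 on the lower side, together 28.0% where chance gives 25%. The Dnah11 call ended without background correction (log2 2.07, SE 0.16, limma adjusted p = 0.101). It also ended with a dye term and litter as a random replicate block (log2 2.66 as before, SE 0.37 in place of 0.19, limma adjusted p = 0.0756, or 0.0135 without the dye term). Over 18 alternatives the limma adjusted p of Dnah11 ran from 7.5e-31 to 0.101. The lowest came without litter 2, where eBayes estimated infinite prior degrees of freedom, against 5.30 in the main fit, so its size means little. The count of probes was 3, 23 and 12 without litters 1, 2 and 3 in turn.

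None of the other genes named next by p passed the threshold; the adjusted p was 0.58 for each of the higher ones. On the higher side stood Anks1b, a postsynaptic scaffold (1.18 ± 0.50), Lhfpl3 (1.12 ± 0.48), the glutamine transporter Slc38a1 (1.12 ± 0.49), the PACAP receptor Adcyap1r1 (1.05 ± 0.46) and the Notch ligand Dll1 (1.03 ± 0.42). Sod1, the cytosolic superoxide dismutase whose extra copy is disrupted in Ts1Cje, was at 0.92 ± 0.29 (1.89-fold), with litter values of 1.25, 0.77 and 0.73, and above 0 on 6 of 6 arrays. Pigr, which carries immunoglobulins across epithelia, stood at 0.91 ± 0.18, the transcription factor Klf13 at 0.85 ± 0.27 and the trafficking protein Tom1l2 at 0.79 ± 0.17. The wild-type channel was above background on 1 array for Lhfpl3, on 2 for Anks1b and Dll1, on 4 for Pigr and Adcyap1r1, and on 6 for Sod1, Slc38a1 and Klf13.

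On the lower side the same ranking gave Olfml3, a secreted matrix protein (-1.37 ± 1.01), the carbonic anhydrase Car3 (-1.21 ± 0.79, saturated on 1 array), Frrs1l, a partner of AMPA receptors (-0.74 ± 0.49), the amino acid transporter Slc7a8 (-0.72 ± 0.24) and Rapgef4, a cAMP-activated exchange factor (-0.71 ± 0.33). Mob3b stood at -0.62 ± 0.22, the peptide hormone Guca2b at -0.51 ± 0.08 and the phosphatase Ptpn22 at -0.50 ± 0.10. A second probe for Mob3b gave -0.25. The Ts1Cje channel was above background on 1 array for Guca2b, on 2 for Frrs1l and on 3 for Mob3b and Rapgef4. In litters 1, 2 and 3 Guca2b stood at -0.36, -0.12 and 0.20 with Ts1Cje in Cy5, but at -0.81, -0.74 and -1.24 in Cy3. Its small SD between litters thus hides a dye difference, and Slc7a8 differed by dye in the same direction. Csn3, a milk casein, and Ankrd29 were also lower in each litter, but their Ts1Cje channel was not well above background on any array and no fold is given. The adjusted p was 0.627 for Slc7a8 and 0.633 for the rest.

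**Figure D3:**
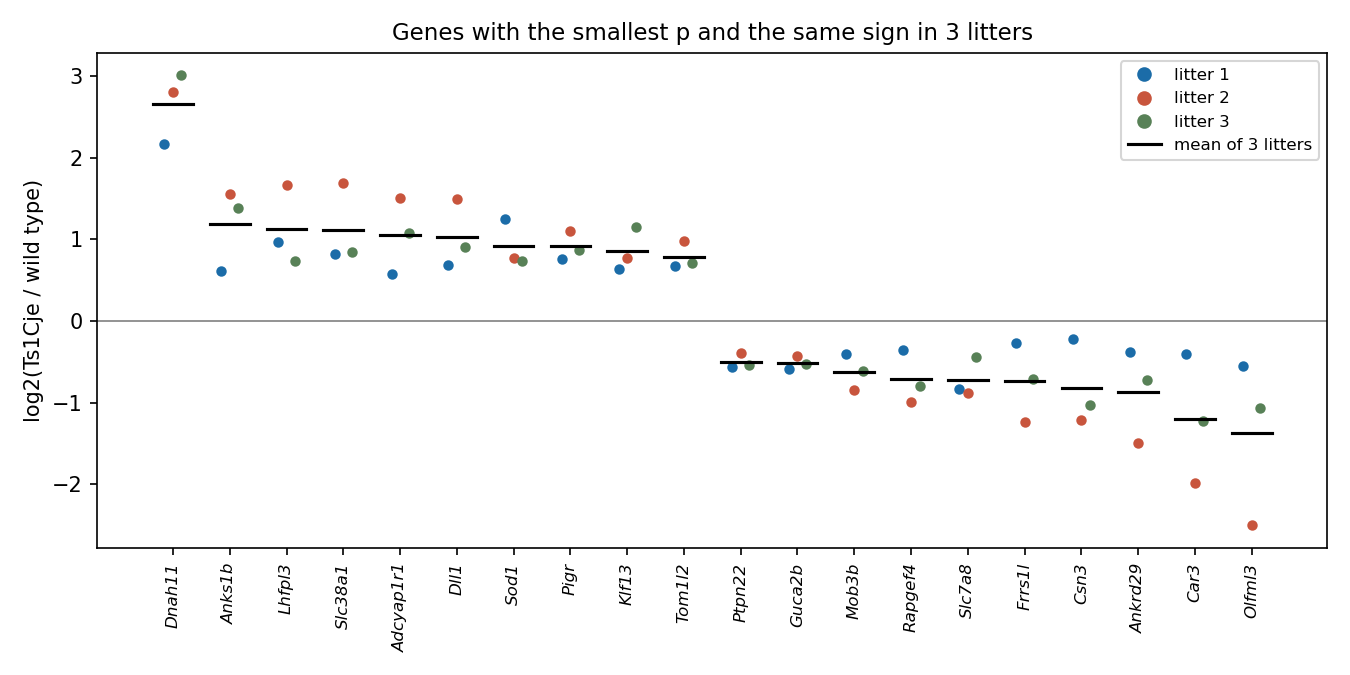
Log2 ratios of Ts1Cje over wild type (vertical axis) for the genes with the smallest p and the same sign in each litter, 10 higher and 10 lower (horizontal axis); points are the 3 litters and black bars their mean. Dnah11 alone passed the threshold, at 2.66.

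The series is about whether slow cycling of these cells goes with changed expression. Genes of G2/M and mitosis had a median of -0.30 over 20 measured members, 19 of them below 0, and genes of DNA replication a median of -0.27 over 20 members, 18 below 0. Both lists fell against all other genes with the preset correlation of 0.01 (camera adjusted p = 8.4e-06 and 0.00037). The correlation estimated from these data was 0.50 for mitosis and 0.46 for replication, far above the preset. With it both calls were lost (camera adjusted p = 0.836 for each). They were also lost without litter 2, where the medians were -0.08 and -0.01. Each list passed in 17 of 20 alternatives, but all except the estimated correlation kept the preset. Litters disagreed on both: the mitosis medians were 0.16, -0.87 and -0.29, and those of replication 0.08, -0.73 and -0.23. The median over all genes was 0.09 in litter 1, 0.00071 in litter 2 and -0.02 in litter 3. Against all genes the replication list was thus not raised in litter 1, and the mitosis list only slightly. No member of either list passed in limma over all probes, nor adjusted over the list alone, and 2 mitosis genes and 1 replication gene were lower at an unadjusted p under 0.05. Xist, the RNA of X inactivation, examined after its values were seen, also lay on opposite sides in these litters, at 2.34, -2.61 and 0.64. Among mitosis genes the motor protein Cenpe was at -0.60 ± 0.52 and the anaphase activator Cdc20 at -0.35 ± 0.05, and Cdk1, the mitotic kinase, at 0.02 ± 0.14 and Anln, a cytokinesis scaffold, at -0.03 ± 0.73 were the least reduced by moderated t. The proliferation marker Mki67 was at -0.30 ± 0.59. Among replication genes the polymerase subunits Pold1 (-0.40 ± 0.11) and Pola1 (-0.31 ± 0.04) had the lowest moderated t, and Pole (0.13 ± 0.16) and Gins4 (0.06 ± 0.07) the highest. The Ts1Cje channel of Pold1 and that of Pola1 were each above background on only 1 array.

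Regulators of the G1/S transition had a median of -0.12 over 14 measured members and did not pass (camera adjusted p = 0.129, and 0.836 with an estimated correlation). The D-type cyclins showed the widest litter spread in that list: Ccnd1 was at 0.61, -2.93 and -0.69 in the 3 litters and Ccnd2 at 0.89, -2.66 and -1.33. The retinoblastoma genes Rb1 (0.24 ± 0.21) and Rbl2 (0.10 ± 0.12) were highest. Inhibitors of cyclin-dependent kinases and p53 targets had a median of -0.10 over 16 members and did not pass (adjusted p = 0.506). The inhibitor Cdkn1b stood at 0.30 ± 0.22 and the antiproliferative Btg2 at 0.27 ± 0.29, against -0.40 ± 0.45 for Cdkn2a, -0.22 ± 0.19 for the stress gene Gadd45a and -0.23 ± 0.65 for Cdkn1a. No member of either list passed over all probes or adjusted over the list alone, and none had an unadjusted p under 0.05 in limma. With median centring of each array in place of loess the G1/S median was 0.0024, the mean was -0.16, and the list passed as lower.

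Neural precursor and radial glia markers rose as a group, with a median of 0.22 over 21 measured members. The camera adjusted p was 0.000761 with the preset correlation, but 0.836 with the estimated one of 0.13. Among the 21, 10 were higher in all 3 litters and none lower in all 3, and the litter medians were 0.36, 0.21 and 0.08. Dll1 passed when adjusted over the list alone (adjusted p = 0.0147), and no member did over all probes, where 5 were higher and 1 lower at an unadjusted p under 0.05 in limma. The RNA-binding stem cell marker Msi1 was next by moderated t at 0.54 ± 0.11, while the matrix protein Tnc (-0.90 ± 1.11) and the receptor Fgfr1 (-0.18 ± 0.32) were lowest by it. The call was lost without litter 1, where the median was 0.16, and on the 3 arrays with Ts1Cje in Cy5, where it was 0.06.

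Astrocyte markers also rose as a group, with a median of 0.22 over 9 members. The camera adjusted p was 0.0413 with the preset correlation, but 0.836 with the estimated one of 0.32. Litter medians were 0.13, 0.62 and 0.03, and the call was lost without litter 2, where the median was 0.08, and without litter 1, where it was 0.29. The list passed in 14 of 20 alternatives, all 14 with the preset correlation. Adjusted over the list alone, 2 members passed and were higher: Clu, a secreted chaperone (0.77 ± 0.30, adjusted p = 0.0176), and the water channel Aqp4 (1.49 ± 1.19, adjusted p = 0.0253), which stood at 2.85 in litter 2. Clu lost this call without litter 3 (0.74) and Aqp4 on the 3 arrays with Ts1Cje in Cy5 (1.32). Neither passed over all probes. Glutamine synthetase, Glul, was at -0.26 ± 0.50 and the calcium-binding S100b at -0.15 ± 0.23.

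Neuronal markers had a median of 0.07 over 12 members and oligodendrocyte lineage markers outside the segment a median of 0.11 over 7, and neither passed (camera adjusted p = 0.0811 and 0.217, and 0.836 for both with an estimated correlation). The microtubule protein Mapt was at 0.61 ± 0.43 and the transcription factor Neurod6 at 0.54 ± 0.30, against -0.11 ± 0.05 for the synaptic vesicle protein Syn1 and -0.05 ± 0.34 for Neurog1. In litters 1, 2 and 3 Syn1 stood at 0.42, 0.29 and 0.24 with Ts1Cje in Cy5, but at -0.60, -0.45 and -0.57 in Cy3. Its small SD between litters thus hides a dye difference. Of the oligodendrocyte lineage, the myelin enzyme Cnp was at 0.50 ± 0.64 and Sox10 at 0.21 ± 0.09, with Cspg4 lowest at -0.20 ± 0.44, followed by Opcml at 0.07 ± 0.53.

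Markers of cell types that neurospheres should hold little of were measured in part. Of those on the array, 3 of 14 microglial, 4 of 11 endothelial, 4 of 15 fibroblast and 1 of 6 red blood cell markers were measured. Among all genes named on the array the count was 6731 of 18501, a share like that of the endothelial markers. Of microglia and macrophage markers 3 were measured, with a median of -0.28 (camera adjusted p = 0.0573, and 0.836 with the estimated correlation of 0.69). Litter medians were 0.19, -0.31 and -0.72. The median was below 0 in each of 19 alternatives, and the list passed in 8, all with the preset correlation. Cd14, a lipopolysaccharide co-receptor, led at -1.20 ± 1.32 (0.31, -1.75 and -2.15 in the 3 litters). The complement genes C1qa and C1qc were at -0.28 ± 0.46 and -0.09 ± 0.02. C1qc differed by dye, at 0.05, -0.03 and 0.16 with Ts1Cje in Cy5 but -0.21, -0.12 and -0.40 in Cy3. The 4 measured endothelial markers had a median of 0.08 (camera adjusted p = 0.575), from Vwf at 0.24 ± 0.13 and Esam at 0.14 ± 0.11 to Flt1 at 0.02 ± 0.16 and Eng at -0.11 ± 0.28. Vwf differed by dye too, at 0.13, -0.23 and -0.59 with Ts1Cje in Cy5 but 0.42, 0.91 and 0.78 in Cy3. The 4 fibroblast and meningeal markers had a median of 0.05 (adjusted p = 0.752), from Mgp at 0.16 ± 0.09 and Thy1 at 0.15 ± 0.17 to the collagens Col1a2 at -0.04 ± 0.20 and Col1a1 at -0.07 ± 0.33. Of red blood cell markers 1 was measured. When adjusted over the list alone, or over all probes, no member of these lists or of the neuronal and oligodendrocyte lists passed.

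**Figure D4:**
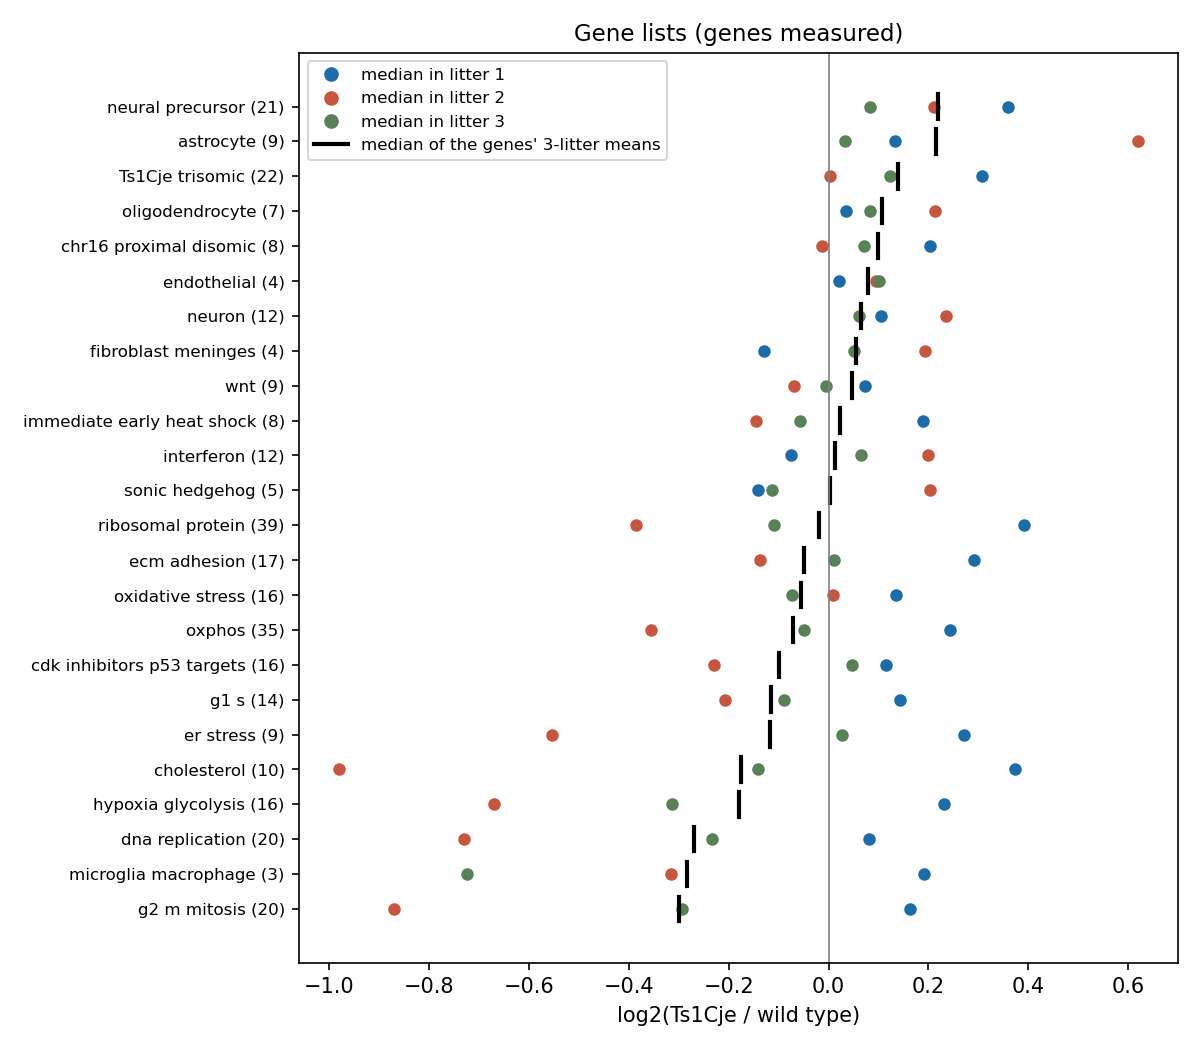
Median log2 ratio of Ts1Cje over wild type (horizontal axis) of each gene list with at least 3 measured genes (vertical axis, number measured in brackets); points are the medians of the 3 litters, black bars the median of the genes' means over litters. The mitosis list is lowest at -0.30 and the neural precursor list highest at 0.22, and litter 2 lies far below litter 1 in the mitosis, cholesterol and ribosomal protein lists.

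Genes of the hypoxia response and glycolysis had a median of -0.18 over 16 members, 14 below 0, and genes of cholesterol synthesis a median of -0.18 over 10, all 10 below 0. Both fell as groups with the preset correlation (camera adjusted p = 0.00157 and 0.0413). The estimated correlation was 0.79 and 0.57, far above the preset, and with it both calls were lost (camera adjusted p = 0.836 for both). They were also lost without litter 2, where the medians were -0.07 and 0.045. The first passed in 16 of 20 alternatives and the second in 12, all except the estimated correlation with the preset. Litter medians were 0.23, -0.67 and -0.31 for the first and 0.37, -0.98 and -0.14 for the second. The glucose transporter Slc2a1, lowest by moderated t, was at -0.75 ± 0.54, while the neuronal glucose transporter Slc2a3 (0.21 ± 0.37) and the oxygen sensor Egln3 (0.0016 ± 0.50) were highest; Vegfa, which promotes vessel growth, was not well above background in Ts1Cje on any array with either of its probes, both lower in the mean, and is given no fold. The sterol enzymes Nsdhl (-0.59 ± 1.13) and Cyp51 (-0.54 ± 0.75) were lowest in their list, and Dhcr7 (-0.04 ± 0.80) and Lss (-0.04 ± 0.24) highest. Cytosolic ribosomal proteins had a median of -0.02 over 39 members and oxidative phosphorylation one of -0.07 over 35, and neither passed (camera adjusted p = 0.379 and 0.236). Litters differed there too, with medians of 0.39, -0.39 and -0.11 for ribosomal proteins and 0.24, -0.36 and -0.05 for oxidative phosphorylation. The ribosomal protein median passed as higher without litter 2 (0.19) and as lower without litter 1 (-0.23). By moderated t the ribosomal proteins ranged from Rps3 (0.12 ± 0.42) and Rpl27 (0.10 ± 0.27) to Rpl32 (-0.25 ± 0.38) and Rpl6 (-0.23 ± 0.34). Respiratory chain members ranged, in the same order, from Cox6a1 (0.20 ± 0.28) and Ndufs3 (0.12 ± 0.17) to cytochrome c, Cycs (-0.36 ± 0.62), and Cox5b (-0.22 ± 0.35). No member of these 4 lists passed, over all probes or adjusted over the list alone.

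Antioxidant genes had a median of -0.05 over 16 members, a mean of 0.06, and no shift (camera adjusted p = 0.847). Its median and mean differ in sign. Sod1 passed when adjusted over the list alone (adjusted p = 0.00995), and no member did over all probes. The glutathione peroxidase Gpx1 stood at 0.32 ± 0.05 and extracellular superoxide dismutase, Sod3, at -0.16 ± 0.22; Gpx3 was not well above background in Ts1Cje on any array. Interferon-response genes outside the segment had a median of 0.01 over 12 members (adjusted p = 0.457), with Gbp2 at 0.58 ± 0.14 and the class I molecule H2-D1 at 0.42 ± 0.18, and with Psmb9 at -0.20 ± 0.09 and Oas1a at -0.10 ± 0.25. Hedgehog genes had a median of 0.0024 over 5 members and Wnt genes one of 0.05 over 9 (adjusted p = 0.98 and 0.786). The receptor Ptch1 was at 0.28 ± 0.58 and Sufu at 0.20 ± 0.33, above Gli2 at -0.26 ± 0.22 and Gli3 at -0.06 ± 0.36, with a second probe for Gli3 at -0.33 and for Ptch1 at 0.26. Of the Wnt genes, Fzd3 (0.36 ± 0.27) and Wnt5a (0.26 ± 0.30) were highest, and Fzd2 (-0.18 ± 0.19) and Fzd5 (-0.13 ± 0.28) lowest.

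Extracellular matrix and adhesion genes (median -0.05 over 17, adjusted p = 0.996), immediate early and heat shock genes (median 0.02 and mean -0.03 over 8, adjusted p = 0.98) and genes of endoplasmic reticulum stress (median -0.12 over 9, adjusted p = 0.47) did not pass. The brain proteoglycans Bcan (0.42 ± 0.41) and Vcan (0.36 ± 0.31) were the highest matrix genes by moderated t, and Tnc and the cadherin Cdh4 (-0.37 ± 0.61) the lowest. Fos stood at 0.43 ± 0.47, Hspb1 at 0.21 ± 0.02 and Jun at -0.23 ± 0.17, and Ier3 was not well above background in Ts1Cje on any array. Among stress genes the chaperone Pdia4 was at 0.21 ± 0.12 and Trib3 at 0.10 ± 0.28, against -0.62 ± 1.05 for asparagine synthetase, Asns, and -0.28 ± 0.76 for Phgdh of serine synthesis. No member of these 3 lists, nor of the interferon, hedgehog and Wnt lists, passed over all probes or adjusted over the list alone. Of 22 lists outside the copy number groups, 6 passed with the preset correlation, none with an estimated one and none by fry, and no list had an unadjusted p under 0.05 with an estimated correlation.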

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

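All tests of explanations in this part were chosen after the results were seen. Repeated control spots, which entered no comparison, carried signal above the buffer spots, and this brought them up here: 257 spots of Gapdh, a glycolytic enzyme, had a mean log2 ratio of Ts1Cje over wild type of -0.42 ± 0.49 (litters 0.10, -0.88 and -0.47), and 257 spots of Actb, cytoplasmic actin, 0.11 ± 0.20 (litters 0.29, -0.11 and 0.13). On each array at least 98.8% of the Gapdh and 98.4% of the Actb spots were brighter than a level near the top of the buffer spots. No test was run on them.

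Dnah11 was higher in Ts1Cje by 2.66 although Ts1Cje carries this part of chromosome 12 in 1 copy. Dye bias is argued against by the lowest of the 6 arrays, 1.99 (SD over arrays 0.77), since both orientations lie on the same side. Cross-hybridisation with other measured axonemal dynein transcripts is argued against by the highest of 5 such genes, 0.092 (SD 0.14). A rise of all genes at that end is argued against by the median of the 9 nearest measured genes, -0.023 (SD 0.07). Besides Dnah11 only Sp4 of the distal list was measured, so most of these 9 lie outside that list. Their median cannot exclude a rise of a few neighbours. A hypothesis left open is a change at the locus itself, which the translocation may bring, and no value here tests it. In limma 1 probe passed, and turning the sign of litters gave 1 of 4 sign turns with as many (highest other 0), which is too few turns to give a share under 0.05.

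Trisomic genes had a median of 0.14, under the 0.58 of 3 copies over 2. Compression of ratios at dim spots may contribute: the brighter 11 genes exceeded the dimmer 11 by 0.19 (0.25 against 0.06, permutation p = 0.162), which leaves it open. Wild-type embryos in the Ts1Cje pool of litter 2 are argued against as the whole cause by the higher list median of the other litters, 0.31, which lies below 0.58 by more than the SD of the litter medians (0.15). For the median of 0.0030 in litter 2 itself they are argued against by Dnah11, which there differed from the mean of the other litters by 0.22 (SD over litters 0.44): reaching it from the mean of the other litters would take 98.7% wild-type RNA, which would bring Dnah11 to 0.091, and it stood at 2.81.

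Mitosis genes lay on opposite sides of 0 in litters 1 and 2 (medians 0.16 and -0.87, difference 1.03). The median over all genes was 0.09 in litter 1, so part of its value above 0 is shared by all genes. Dye bias is argued against in litter 2 by the higher of its arrays, -0.65. In litter 1 the lower array stood at 0.0062, under the medians of all tested probes on the arrays of that litter (0.08 and 0.04). A rise of the list in litter 1 therefore rests on 1 array. A drift of ratios with spot brightness could not be tested separately, because the loess within each array had already removed such a drift. In the normalized ratios, 10000 random lists matched on brightness differed by at most 0.72. That outcome was largely set by the loess. Different shares of female embryos in the pools may differ along with them: Xist differed by 4.95 between these litters, but with 1 pool per genotype and litter, sex and any other difference between pools cannot be told apart. Of 4 sign turns, the real one included, 2 gave at least the real count of 6 lists. The count was 9 with litter 1 turned and 5 with litter 2 or litter 3 turned. Turning litter 1 thus gave more lists than the real signs did, so the count of 6 does not set the real signs apart. With 4 turns a share under 0.05 could not arise in any case.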

How the results depend on the processing

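The window scan's alternatives, the litter value from 1 array and the centring of each litter were chosen after the results were seen. The count of 1 probe was the same in 13 of 21 alternatives, including the 6 arrays with litter as a random replicate block (1; correlation within litters 0.34). It was 0 without background correction (429 probes at an unadjusted p under 0.05 in limma) and 0 with a dye term added to the replicate block (511). It was 55 with median centring, 23 on the Cy5 orientation alone (22 lower), 74 on the Cy3 orientation alone (72 higher), and 3 to 23 without 1 litter. Of 19 probes past in both orientations, 18 had opposite directions, which dye bias brings. Under median centring and without litter 2 or litter 3 the estimated prior degrees of freedom were infinite, against 5.30. Dnah11 ranged from 2.07 to 3.00 and Sod1 from 0.75 to 1.01 over 18 alternatives.

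The trisomic median stayed positive, 0.03 to 0.23, and the list passed in 19 of 20 alternatives, all 19 with the preset correlation. With an estimated correlation the median was 0.14 and the list did not pass (camera p = 0.231). The proximal median, 0.02 to 0.15, passed in none of 20. The distal chromosome 12 median was 0.93 without background correction, -0.078 with no filter (4 genes measured), 2.66 with the filter on each array (Dnah11 alone) and 1.34 without the litter 3 array with Ts1Cje in Cy5. The highest window passed with no filter (0.30), on the Cy5 orientation alone (0.35), without the litter 3 Cy5 array (0.31) and with a litter value from 1 array (0.32), and lay between 0.25 and 0.41 without 1 litter; it was in the segment in 14 of 19 alternatives.

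The count of 6 lists was 1 on the Cy3 orientation alone, 0 with an estimated correlation, 3 to 9 without 1 litter, and 8 with litter as a random replicate block. The G1/S median turned to 0.0024 with median centring, though the mean (-0.16) and the direction of the test stayed lower. Without 1 litter the cholesterol median ran from -0.57 to 0.045 and the ribosomal protein median from -0.23 to 0.19, both positive without litter 2. Of 436 values of single lists, 389 kept direction and side of the threshold or changed sign uncalled (35), 26 lost and 18 gained a call and 3 medians turned, those just given. Of 89 values of calls adjusted over the list alone, 3 lost the call (Son and Aqp4 on the Cy5 orientation alone, Clu without litter 3). Of 2442 values of named genes, 2386 did so, 2 lost a call (Dnah11), 54 gained one and 0 turned. Aquantile leaves ratios as they are. Except where a cause is named, the cause was not tested. Few probes, 23.3% to 59.2% per array, stood above background, which limits how many genes were measured.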

Other observations

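Some further genes, all picked after their values were seen, had litter ratios far apart, a difference that was not tested. Between litters 1 and 2, 40 genes differed by more than 2 on the log2 scale, 31 higher in litter 1 and 9 in litter 2. In litter 2 the genes below wild type included the chromatin proteins Hmga1 (0.51, -1.85 and -0.28 in litters 1, 2 and 3) and Hmga2 (0.52, -1.72 and -0.59) and the galectin Lgals1 (0.51, -1.90 and 0.39). On the other side stood Txnip, an inhibitor of thioredoxin (-0.04, 2.52 and 0.31), the urea transporter Slc14a1 (-0.33, 2.30 and 0.60), the gap junction protein Gja1 (-0.26, 1.81 and 0.0099) and Ndrg2 (-0.11, 1.96 and 0.12). Xist (2.34, -2.61 and 0.64) was accompanied by the X-linked Eif2s3x (0.81, -0.69 and 0.23) and by probes named Nrp2 (2.72, -3.36 and 0.61) and Olfr1238 (1.83, -2.80 and 0.61); whether these probes measure the genes they are named for was not tested.

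A hypothesis formed after seeing the list medians is that mitotic RNA may be lower relative to ribosomal protein RNA in Ts1Cje in each litter. The mitosis median minus the ribosomal protein median was -0.23, -0.48 and -0.18 in the 3 litters (mean -0.30 ± 0.16), and for replication -0.31, -0.34 and -0.13. Both differences were larger than their spread between litters (SD 0.16 and 0.12). An exact sign-flip test over 3 litters gives at best 0.25 and leaves the hypothesis open.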
